A study of Saccharomyces cerevisiae with 19 samples.

How the data were processed

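Sir3 binding was measured by ChIP-chip in Saccharomyces cerevisiae on 19 two-colour tiling arrays in 11 groups. Per the labels, cells growing exponentially in rich medium were fixed with formaldehyde and chromatin was precipitated with an antibody against Sir3. The precipitated DNA was labelled in Cy5 and DNA of the whole cell extract in Cy3, both after amplification by random-primer extension and PCR. There were 8 groups of 2 arrays. The groups pGPD-SIR3 in strain yAT2554, pGPD-SIR2, and pGPD-SIR3 in strain yAT2476 had 1 array each. The arrays came in a first deposit of 12 and a later deposit of 7; the later one held a replicate each of pADH-SIR3, pTEF-SIR3 and pGPD-SIR2 pGPD-SIR3, and all 4 arrays released from nicotinamide. Nothing in the labels says that replicates were separate cultures. The p-values therefore measure only the spread between these arrays, which may be technical.

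Each deposited sample file held, per probe, a ratio of precipitated over input signal, a rescaled ratio, and a score. Checked on the values, the rescaled ratio was the ratio times 1 factor per array, with missing probes filled and 1 to 16 measured values per array replaced as well: 7271 of 7275 filled probes with both flanks measured equalled the mean of these flanks within a relative tolerance of 0.0001. The authors' series table equalled this rescaled ratio in 787683 of 787683 cells. The deposited score was the ratio minus its mean, divided by its SD on the array. On 5 arrays between 1 and 7 deposited ratios lay at or below 0, and these values were set to missing. The scanner, background correction and spot filter of the authors are not given in the sources used here, and channel intensities were not used here.

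The unfilled ratio was used. Of 45220 spots, 41480 were chromosomal probes; none of the 295 mitochondrial probes had a ratio (0 measured). Between 40247 and 41270 chromosomal probes (97.0% to 99.5%) had a ratio per array, and 36515 (88.0%) had one on every array. The median ratio of an array ran from 0.0292 to 0.942, so each array was put on the log2 scale and centred on its median, without loess or quantile normalization. All signals below are such log2 ratios, so a value of 0 stands for the typical probe of that array and not for absence of Sir3. The number of arrays limits the precision.

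The genome build behind the probe coordinates is not given in the sources used here. Probe positions are printed as the files give them, and gene names were placed by R64 coordinates with a margin. To measure the offset between both, R64 coding positions were shifted in steps of 25 bp against the log2 ratios of the A2Q arrays. The best shift lay within 75 bp for 14 chromosomes, at 250 bp for chromosome 10 and at 225 bp for chromosome 11. Probes at least 100 bp inside a gene were averaged (450 bp on the upper side for chromosomes 10 and 11), with at least 2 probes measured on all 19 arrays. This gave 4214 genes with 21778 probes, a median of 4 per gene; 404 lay within 50 kb of a chromosome end and 378 lay on chromosomes 10 and 11. Distances run from the start of the coordinates on left ends and from the outermost gene or probe on right ends.

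Groups were compared with limma 3.58.1 in R 4.3.3: a linear model with 1 mean per group over all 19 arrays, with 8 residual degrees of freedom and empirical Bayes moderation (4.28 prior degrees of freedom). Benjamini-Hochberg adjustment was made within each of 13 comparisons at 0.05. A group of 1 array is assumed to vary like the others. The same model was fitted to 144 zones: mean log2 ratios of at least 3 probes in windows of 0 to 5, 5 to 10, 10 to 15, 15 to 20, 20 to 30 and 30 to 50 kb from the 32 chromosome ends. Covered length was counted per array, without a test, over 1295 bins of 1 kb within 50 kb of the ends. A bin counted as covered when it exceeded the median of bins over 50 kb from every end by 3 scaled MADs. Internal bins and genes left out HML, HMR and the rDNA with 10 kb on either side. Files were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

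The comparisons, the tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Per comparison the rule named the 8 largest rises and 8 largest falls among genes past 0.05 whose arrays did not overlap between the groups. It took at most 2 per chromosome arm and direction. It added the 3 largest changes past 0.05 in each list, and the silent mating loci, YFR057W, SIR3, SIR2, DOT1 and PPR1 whatever their values. For zones it named the 5 largest changes past 0.05 in each direction.

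The lists covered silent mating loci, loci altered in the strains, Y' helicase genes, the COS family, the seripauperin, DAN and TIR mannoproteins, flocculins, subtelomeric sugar genes, thiamine and vitamin B6 genes, iron uptake, the phosphate regulon, aryl-alcohol dehydrogenases, HSP31 paralogs, highly transcribed glycolytic and elongation genes, ribosomal proteins, tRNA genes, and internal control genes. Of the Y' helicase and tRNA lists 0 members were measured. Lists with enough members (11) were tested with limma's camera, at its preset correlation and at an estimated one.

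The same fit was tested on simulated data, with 200 of 4214 genes shifted on noise of the observed spread. At a shift of 0.5 it recovered from 44.8% to 83.6% of the shifted genes across comparisons, at a shift of 1 from 91% to 100%, and at a shift of 2 from 98.5% to 100%. Wrong calls made up 1.6% to 8.2% of calls. The noise was independent between genes and arrays, with the same spread in every group and no deposit effect. These rates may therefore not carry over to the real arrays.

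Alternatives were scaling each array by the MAD of internal genes, the authors' filled values, at least 4 probes per gene, single probes, only the groups compared, slide as a random block (correlation 0.138, slide known for the first deposit), deposit or replicate number as a fixed block, and leaving out each array. Further alternatives were chosen after seeing the data: probes at least 300 bp inside the gene, the probes measured on each array, either deposit alone, a fixed log2 threshold of 1 for covered length, and the interaction of SIR2 and SIR3 with pGPD-SIR3 from yAT1254. A mock precipitation was not used here.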

Results

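Binding of the silencing protein Sir3 was profiled by ChIP-chip on 19 two-colour arrays of budding yeast, in 11 groups. WT was strain yAT191. SIR3 was driven by the ADH, TEF or GPD promoter at its own locus (pADH-SIR3, pTEF-SIR3, pGPD-SIR3), a series meant to give rising SIR3 expression. SIR3 expression itself was not measured here. The pGPD-SIR3 construct was carried by 3 strain backgrounds, yAT1254, yAT2554 and yAT2476, and "pGPD-SIR3" without a strain name stands for yAT1254 here. The other groups overexpressed SIR2, SIR2 with SIR3, or the SIR3-A2Q point mutant, used by the study to look at telomere clustering. A last pair of groups was pGPD-SIR3 and a pGPD-SIR3 strain labelled dot1, sampled 8 h after release from 5 mM nicotinamide (NAM), an inhibitor of the deacetylase Sir2. Dot1 is the histone H3 lysine 79 methyltransferase, and "dot1" stands for the arrays so labelled. Groups had 2 arrays, apart from yAT2554, yAT2476 and pGPD-SIR2 with 1, whose values have no SD. Between 40247 and 41270 of 41480 chromosomal probes had a value per array. Correlations between replicates over probes, which are not independent replicates, ran from 0.730 (A2Q) and 0.743 (WT) to 0.976 (dot1).

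The labels' deletions were looked for in the probes. In pADH-SIR3, pTEF-SIR3 and yAT2554, labelled as lacking HML, 4 of the 5 HML probes were missing on every array, against 0 of 5 in WT. In WT, pGPD-SIR3, A2Q and both NAM groups, labelled with a truncated left end of chromosome 7 at ADH4, 22 or 23 of the 27 probes from that end to ADH4 were missing, against 0 or 1 in the other strains. Genes beside these breakpoints (CHA1 and VAC17 at HML, ZRT1 and FZF1 at ADH4) thus differ in their surroundings between strains. In the strains labelled as lacking PPR1, 4 adjacent probes at its upstream edge (174817 to 175411 on chromosome 12) had 39 of 40 values missing on 10 arrays, against 0 of 36 on the other arrays, while 108 of 120 values of the probes within the gene were measured. At DOT1 no such stretch was seen: on the 2 arrays labelled dot1, 9 of 10 probe values were measured, with a mean signal of -0.13 ± 0.28 (SD, n = 2). Absence of DOT1 thus rests on the label.

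In WT, Sir3 signal was highest at the silent mating loci and at the chromosome ends. The mean log2 ratio was 7.65 ± 0.04 at HML and 7.24 ± 0.19 at HMR (SD, n = 2), 6.73 ± 0.38 at the subtelomeric gene YFR057W, near the right end of chromosome 6, and 3.53 ± 0.84 at the rDNA probes. Across ends it fell from a mean of 3.76 in the outer 0 to 5 kb to 1.67 at 10 to 15 kb and 0.34 at 20 to 30 kb. These means cover 10, 22 and 31 zones, so not the same ends. With the TEF and GPD promoters the signal at 10 to 15 kb was 3.94 and 4.41, and that at 20 to 30 kb 1.26 and 1.31. Means and profiles over ends include the loci altered in the strains. At HML, 10 to 15 kb from the left end of chromosome 3, the zone was at 7.19 in WT. It was at 2.68 with pADH-SIR3 and 3.01 with pTEF-SIR3, labelled as lacking HML, which lowers their means against WT. The mean profile fell below a log2 ratio of 1 at 14 and 17 kb on the WT arrays, at 17 and 18 kb with pADH-SIR3, at 25 and 26 kb with pTEF-SIR3 and at 26 kb on both pGPD-SIR3 arrays. Strains yAT2554 and yAT2476 also reached 26 kb, whereas both A2Q arrays fell below 1 at 2 kb.

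**Figure D1:**
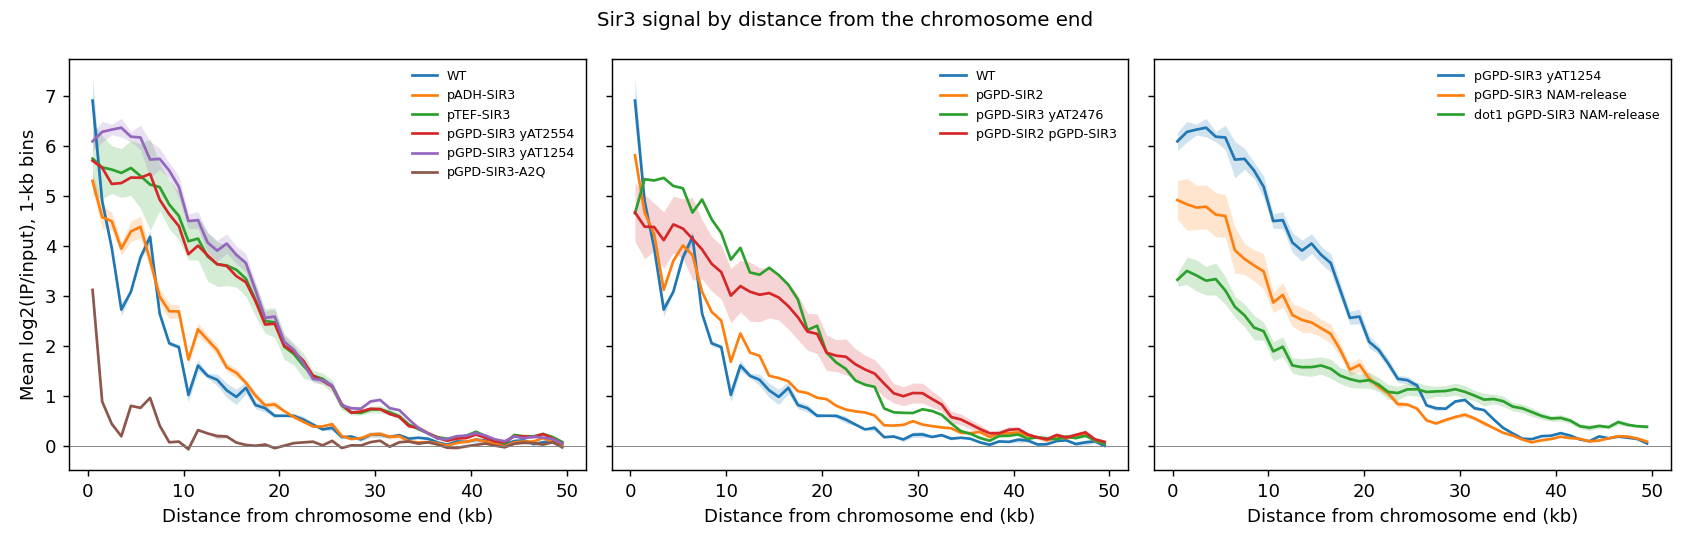
Mean log2 ratio of precipitated over input DNA (y axis) in 1-kb bins against the distance from the chromosome end in kb (x axis, 0 to 50), with lines for group means and shading for the range of the arrays. The WT profile falls below 1 at 14 and 17 kb and the pGPD-SIR3 profile at 26 kb on both arrays.

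The length covered by Sir3 within 50 kb of the 32 ends was larger with the TEF and GPD promoters than in WT. WT arrays had 263.5 ± 57.3 kb of 1295 1-kb bins covered (SD, n = 2), pADH-SIR3 303 ± 22.6 kb, pTEF-SIR3 502.5 ± 36.1 kb and pGPD-SIR3 528.5 ± 13.4 kb. The single arrays of yAT2554 and yAT2476 had 530 and 500 kb, and that of pGPD-SIR2, without SIR3 overexpression, 409 kb. The difference between pADH-SIR3 and WT lay within the spread of the WT arrays (223 and 304 kb), and that between pTEF-SIR3 and pGPD-SIR3 within the spread of the pTEF-SIR3 arrays (477 and 528 kb). Within the first deposit the values were 319 kb for pADH-SIR3 and 528 kb for pTEF-SIR3. These lengths include the ends altered in the strains. The left end of chromosome 3, at HML, had 16 kb in WT and 11 kb with pADH-SIR3, and that of chromosome 7 13 and 11 kb. By end, with ends picked after their values were seen, the left end of chromosome 1 went from 12.5 kb in WT (18 and 7 kb on the 2 arrays) to 32.5 kb with pTEF-SIR3 and 33 kb with pGPD-SIR3, and the left end of chromosome 12 from 7 kb to 23 kb with both. The right end of chromosome 3, which holds HMR, stayed between 26 and 29 kb in WT and the 3 promoter groups. The left end of chromosome 13 stayed between 3.5 and 7.5 kb.

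**Figure D2:**
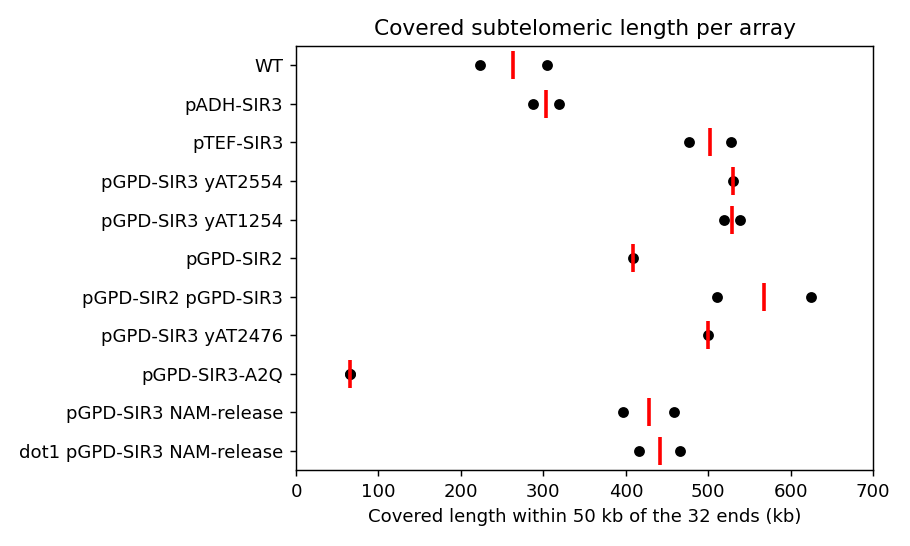
Length covered by Sir3 within 50 kb of the chromosome ends in kb (x axis) for each group (y axis), with points for arrays and a red bar for the group mean. Both A2Q arrays sit at 65 and 66 kb, WT arrays at 223 and 304 kb and pGPD-SIR3 arrays at 519 and 538 kb.

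The comparison of pADH-SIR3 with WT addressed the first step of the promoter series. Sir3 signal rose over a few subtelomeric genes that were weakly bound in WT. At the right end of chromosome 3, YCR101C (probes 302568 to 302899, 13.5 kb from the end) went from 1.15 ± 0.98 to 5.21 ± 0.93 (SD, n = 2 each), a difference of 4.06 (SE 0.50, limma adjusted p = 0.00121). Its neighbour YCR102C, a quinone oxidoreductase-like gene, rose by 3.82 (SE 0.43). At the right end of chromosome 6, YFR054C rose by 3.77 (SE 0.52) and IRC7, encoding a beta-lyase, by 3.46 (SE 0.47). On chromosome 15, YOR389W near the right end rose by 3.13 and the sulfatase gene BDS1 near the left end by 3.12 (SE 0.37), with YOL162W at 2.80. YLR460C on chromosome 12 rose by 2.88. The zones with the largest rises were those at 5 to 10 kb (3.95, SE 0.45) and 10 to 15 kb (3.72) from the right end of chromosome 6, and 10 to 15 kb from the right end of chromosome 3 (3.67).

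In all, limma called 39 of 4214 genes between pADH-SIR3 and WT, 34 higher and 5 lower, with 615 at an unadjusted p under 0.05. Of the higher ones, 18 lay within 50 kb of an end, with a median log2 difference of 3.13, and 16 lay further in, with a median of 0.60. Lower were CHA1, a serine and threonine deaminase gene (-4.70, SE 0.27), and VAC17, a vacuole inheritance gene (-1.64), both beside the HML deletion of the pADH-SIR3 strain. YFR018C (-0.99), the exchange factor gene BUD5 (-0.66) and the biotin synthesis gene BIO3 (-0.56) were also lower. In the zones, 19 of 144 were higher and 3 lower; the latter were 10 to 20 kb from the left end of chromosome 3 and 15 to 20 kb from the left end of chromosome 7, at the breakpoints. At HMRA1 the difference was -2.55 (SE 0.56, adjusted p = 0.0536), and over the SIR3 gene itself 0.61 (SE 0.16, adjusted p = 0.118).

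The acid phosphatase genes PHO5 and PHO3, internal on chromosome 2, rose by 1.19 (SE 0.14) and 1.13 (SE 0.13) with pADH-SIR3, the only 2 of 6 measured phosphate genes past the threshold, also when adjusted over the list alone; the list's camera call at the preset correlation (adjusted p = 0.0114) gave an adjusted p of 0.334 with an estimated correlation. None of the 3 aryl-alcohol dehydrogenase genes passed (0 over all genes), though all 3 did when adjusted over the list alone, with a median of 1.28. None of the subtelomeric sugar genes (0 of 10), iron genes (0 of 12) or flocculins (0 of 5) passed; the medians of the sugar and iron lists were 0.04 and -0.08. The elongation factor gene EFB1 (0.61) was the 1 called member of 11 highly transcribed genes. The count was 296 without WT replicate 1, and 24 and 23 without pADH-SIR3 replicate 1 or 2. It was 27 in the first deposit alone and 42 with the deposit as a block.

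The comparison of pTEF-SIR3 with WT addressed the next promoter of the series, and the rises were both larger and spread over more ends. On the left end of chromosome 5, DLD3, a D-lactate dehydrogenase gene (probes 16538 to 17656, 17.2 kb from the end), went from 0.58 ± 1.05 to 5.23 ± 0.65 (SD, n = 2 each), a difference of 4.65 (SE 0.41, limma adjusted p = 1.24e-05). RMD6, a sporulation gene beside it, rose by 4.61 (SE 0.38). YOR389W rose by 4.55 and BDS1 by 4.54 at opposite ends of chromosome 15. EMA35 (4.53) and YCR102C (4.50) rose near the right end of chromosome 3, YFR054C (4.51) on chromosome 6, and the aspartic protease gene YPS6 (4.48, SE 0.36) on chromosome 9. The largest zone rise was 4.48 (SE 0.38) at 15 to 20 kb from the left end of chromosome 5, from 0.72 to 5.20.

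Many subtelomeric metabolic genes rose with pTEF-SIR3, though no camera call of their lists held with an estimated correlation. Of 10 measured sugar genes 8 were higher (9 adjusted over the list alone), among them the maltose activator gene MAL33 (4.33, SE 0.61), the maltose permease gene MAL31 (4.25) and the isomaltase gene IMA5 (3.52, SE 0.26). Of 12 iron genes 7 were higher (7 adjusted over the list alone), led by the siderophore transporter gene ARN2 (3.94), the ferric reductase gene FRE2 (3.81) and the enterobactin transporter gene ENB1 (3.57). All 3 aryl-alcohol dehydrogenase genes rose (AAD6 2.89, AAD3 2.57, AAD4 1.97), as did COS9 (4.18) and COS10 (2.31) among 4 COS genes (3 adjusted over the list alone), and FLO9 (2.08), FLO5 (0.99) and FLO1 (0.99) among 5 flocculins. Of the phosphate genes, 3 of 6 rose (5 adjusted over the list alone): the phosphate cotransporter gene PHO89 (3.84), PHO3 (1.49) and PHO5 (1.16). The camera calls of these lists at the preset correlation were lost with an estimated correlation, with adjusted p = 0.118 for sugar, 0.153 for iron, aryl-alcohol and COS genes, 0.171 for flocculins and 0.0797 for phosphate.

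Rises were not restricted to the ends. Of 380 called genes between pTEF-SIR3 and WT (344 higher, 36 lower; 1090 at an unadjusted p under 0.05), 111 of the higher ones lay within 50 kb of an end (median 2.04) and 233 further in (median 0.57). The internal ones included EFB1 (1.02), the enolase gene ENO2 (0.91) and the pyruvate kinase gene CDC19 (0.85) among 6 of 11 highly transcribed genes (10 adjusted over the list alone; adjusted p = 0.153 with an estimated correlation), and RPL5 (1.63), RPL3 (1.05) and RPP0 (0.73) among 5 of 68 ribosomal protein genes (11 adjusted over the list alone). Of the 4 mannoprotein genes, TIR3 (0.56) and TIR1 (0.55) rose. PMA1, the plasma membrane proton pump gene, rose by 0.97 (SE 0.13) and ERG25 by 0.55, as 2 of 11 internal controls; the list's median was -0.03 and its mean 0.08. Over SIR3 itself the signal went from 0.31 ± 0.14 to 3.20 ± 0.01, a rise of 2.89 (SE 0.16). CHA1 (-2.99), VAC17 (-1.34) and HMRA1 (-2.30, SE 0.56, adjusted p = 0.0215) were lower, as were CBP3 (-0.71), BUD5 (-0.67), BRE2 (-0.47), VAC14 (-0.43) and AAP1 (-0.42). The count was 740 without WT replicate 1 and 204 without pTEF-SIR3 replicate 2. It was 142 in the first deposit alone and 287 with the deposit as a block; in the zones 81 of 144 were higher and 3, all on the left end of chromosome 3, lower.

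With the last promoter of the series, pGPD-SIR3 against WT in the same truncated-end background, genes near the ends gained signal. DLD3 went from 0.58 ± 1.05 to 6.03 ± 0.36 (SD, n = 2 each), a rise of 5.45 (SE 0.41, limma adjusted p = 3.87e-06). YFR054C rose by 5.37 (SE 0.52), BDS1 by 5.28 (SE 0.37), RMD6 by 5.24, EMA35 by 5.20, YOR389W by 5.17 and YCR101C by 5.16. SEO1, a permease gene 8.2 kb from the left end of chromosome 1 (probes 7322 to 8903), rose by 5.03 (SE 0.39). HMRA1 differed by -0.74 (SE 0.56, adjusted p = 0.502), and YFR057W was at 6.67 ± 0.12 against 6.73 ± 0.38 in WT. In the zones 83 of 144 were higher and 0 lower, with the largest rise of 5.24 (SE 0.52) at 10 to 15 kb from the left end of chromosome 5. By distance, 16 of 22 zones at 10 to 15 kb, 18 of 31 at 20 to 30 kb and 7 of 32 at 30 to 50 kb were higher.

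By list, 9 of 10 sugar genes were higher with pGPD-SIR3 (9 adjusted over the list alone; MAL33 4.77, MAL31 4.50, IMA5 3.52; adjusted p = 0.0519 with an estimated correlation). Of 12 iron genes 7 were higher (8 adjusted over the list alone; ARN2 4.68, ENB1 4.16, FRE2 3.48; adjusted p = 0.0718 with an estimated correlation). Of 4 COS genes 3 were higher (COS9 4.94, COS10 3.25, COS8 2.32), as were all 3 aryl-alcohol genes (AAD3 3.22, AAD6 2.90, AAD4 1.87), both lists with an adjusted p of 0.0718 with an estimated correlation. The phosphate genes PHO89 (3.50), PHO3 (1.62) and PHO5 (1.35) were 3 of 6 (4 adjusted over the list alone), and this list's camera call held with an estimated correlation (adjusted p = 0.0405). FLO9 (2.35) and FLO5 (0.86) rose among 5 flocculins (3 adjusted over the list alone). CDC19 (1.07), ENO2 (0.86) and the pyruvate decarboxylase gene PDC1 (0.53) were among 4 of 11 highly transcribed genes. Of 68 ribosomal protein genes 0 passed in limma, also when adjusted over the list alone, with a median of -0.01 that turned to 0.07 MADs with arrays scaled by their internal spread. PMA1 rose by 1.20 (SE 0.13) and the SIR3 gene by 3.53 (SE 0.16), to 3.84 ± 0.13.

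In all, 327 genes were called between pGPD-SIR3 and WT, 281 higher and 46 lower, with 852 at an unadjusted p under 0.05. Of the higher ones 106 lay within 50 kb of an end (median 2.50) and 175 further in (median 0.55). Of the 46 lower genes 45 were internal and small, with a median of -0.39: RUF21 (-0.86), the proteasome gene PRE2 (-0.75), CBP3 (-0.74), PHO86 (-0.55), GGC1 (-0.55), the septin gene CDC10 (-0.53), MET3 (-0.49) and the porin gene POR1 (-0.47). All arrays of both groups were in the first deposit, which alone gave 194 calls (192 higher). Without WT replicate 1 the count was 834, without WT replicate 2 it was 201, and without pGPD-SIR3 replicate 2 it was 160.

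Between the steps of the series, pTEF-SIR3 had 158 genes above pADH-SIR3 and 0 below in limma, with 458 at an unadjusted p under 0.05. Both strains lack HML. MAL33 went from 0.27 ± 0.07 to 5.21 ± 0.55 (SD, n = 2 each), a rise of 4.94 (SE 0.61, adjusted p = 0.000412), and MAL31 rose by 4.60. RMD6 rose by 4.58, DLD3 by 4.56, COS9 by 4.51 and the glutamate dehydrogenase gene GDH3, 32.3 kb from the left end of chromosome 1 (probes 31804 to 32757), by 4.37 (SE 0.45). The monocarboxylate permease homologue MCH2 (4.25) and DFP4 (4.04) followed. HMRA1 differed by 0.25 (SE 0.56, adjusted p = 0.945), whereas the SIR3 gene rose by 2.28 (SE 0.16). Of the sugar genes 8 of 10 were higher (9 adjusted over the list alone; adjusted p = 0.0651 with an estimated correlation) and of the iron genes 7 of 12 (8 adjusted over the list alone; 0.0882), with FRE2 at 4.21, ENB1 at 3.77 and ARN2 at 3.04. PHO89 (4.12), AAD6 (1.61), FLO9 (1.87), PDC1 (0.59) and PMA1 (0.61) also rose. Of the calls 80 lay within 50 kb of an end (median 1.83) and 78 further in (median 0.61). In the zones 72 of 144 were higher, with fewer calls on scaled arrays, as given further down. The first deposit alone, with 1 array a side, gave 77 calls, the later one 228 (222 higher) and the deposit as a block 195. Counts were 93, 95 and 98 without pADH-SIR3 replicate 1, pADH-SIR3 replicate 2 and pTEF-SIR3 replicate 2, and scaling the arrays by their internal spread gave 41.

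The next step, pGPD-SIR3 in yAT2554 against pTEF-SIR3, compared strains of like genotype beside the promoter. No gene passed (0 of 4214 in limma, 52 at an unadjusted p under 0.05), and 0 of 144 zones passed. The SIR3 gene was at 2.55 in yAT2554 and 3.20 ± 0.01 with pTEF-SIR3, a difference of -0.65 (SE 0.20, adjusted p = 1), and HMRA1 at 4.88 and 4.93 ± 1.12. Zone means at 10 to 15 kb were 3.88 and 3.94. The fit rests on the single yAT2554 array; without pTEF-SIR3 replicate 1 it gave 2 calls, both higher, and the first deposit alone 2, both lower.

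Strain background was addressed by pGPD-SIR3 in 3 strains. Between yAT2554 and yAT1254 limma called 3 genes (532 at an unadjusted p under 0.05). GTT1, a glutathione transferase gene 14.5 kb from the right end of chromosome 9, was at 4.32 in yAT2554 and 1.95 ± 0.20 (SD, n = 2) in yAT1254, a difference of 2.37 (SE 0.36, adjusted p = 0.0416). CHA1 beside the deleted HML was lower by -3.04 (SE 0.33) and the SIR3 gene by -1.28 (SE 0.20, adjusted p = 0.0416). The deviating zones were 15 to 20 kb from the right end of chromosome 9 (1.24) and 10 to 20 kb from the left end of chromosome 3 (-3.50 and -1.73). HMRA1 differed by -1.62 (SE 0.68, adjusted p = 0.366). Both groups lay in the first deposit, which alone gave 8 calls; the deposit as a block gave 6, scaling gave 0, and leaving out pGPD-SIR3 replicate 2 gave 1.

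Strain yAT2476, with an intact left end of chromosome 7, was set against yAT1254 on 1 array, and 215 genes were called, 72 higher and 143 lower (982 at an unadjusted p under 0.05). On the right end of chromosome 14, BSC5 (probes 761361 to 762157, 21.8 kb from the end) was at 0.21 against 4.54 ± 0.28 in yAT1254 (SD, n = 2), a difference of -4.32 (SE 0.28, limma adjusted p = 9.18e-06), and YNR068C beside it differed by -3.14 (SE 0.35). The ornithine aminotransferase gene CAR2 (-2.77) and YHR033W (-2.62) were lower, as were the maltose genes MAL11 (-2.24, SE 0.24) and MAL13 (-2.12) on the right end of chromosome 7, the only 2 of 10 sugar genes called. The zinc transporter gene ZRT1 (-2.73) and the sulfite regulator gene FZF1 (-2.55) were lower beside the breakpoint of yAT1254. The SIR3 gene was lower, at 2.83 against 3.84 ± 0.13 (SE of the difference 0.20, adjusted p = 0.016), and TIR4 differed by -0.55. Of the zones 0 were higher and 6 lower, the largest at 15 to 20 kb from the right end of chromosome 14 (-4.00, SE 0.56) and 5 to 10 kb from the left end of chromosome 13 (-3.55).

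Higher in yAT2476 than in yAT1254 were YAL063C-A (1.65), the dihydroxyacetone kinase gene DAK2 (2.22 against 0.74), the malate dehydrogenase gene MDH2 (1.25, SE 0.15), the alpha-factor receptor gene STE2 (1.22, SE 0.13) and ERG25 (0.57). Of 68 ribosomal protein genes 17 were higher on the single yAT2476 array (44 adjusted over the list alone; median 0.60; camera adjusted p = 0.333 with an estimated correlation), among them RPL31B (1.11), RPL22B (1.02), RPS9B (1.00), RPS9A (0.95) and RPL22A (0.91). All 3 arrays lay in the first deposit, which alone gave 55 calls, and the count was 62 without pGPD-SIR3 replicate 1 and 59 without replicate 2; the deposit as a block gave 243.

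Overexpression of SIR2 was compared with WT on 1 array. The largest rise lay over the SIR2 gene itself, internal on chromosome 4 (probes 377021 to 378049), at 1.01 against -0.03 ± 0.12 in WT (SD, n = 2), a difference of 1.04 (SE 0.15, limma adjusted p = 0.00421). ADE2, which marks the rDNA insertion of this strain per the labels, rose by 0.98 (SE 0.19). SPO74 (0.98), the replication checkpoint gene MRC1 (0.95, SE 0.12), the chitin deacetylase gene CDA2 (0.90), CBS1 (0.89), NBP1 (0.87), FAU1 (0.86) and the siderophore transporter gene ARN1 (0.64) rose. Lower were RPP0, a ribosomal stalk gene (-1.47, SE 0.23), the kinase subunit gene SNF4 (-1.29), the pyruvate dehydrogenase gene LAT1 (-1.22), MSO1 (-1.03), COQ4 (-1.02), MET3 (-0.93), AIM22 (-0.89), the copper regulator gene MAC1 (-0.86) and PPR1 (-0.39), a gene that WT is labelled as lacking although most of its probes were measured there. RPP0 and RPL33A (-0.72) were the only 2 of 68 ribosomal protein genes called (8 adjusted over the list alone).

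Of 99 calls between pGPD-SIR2 and WT, 46 were higher and 53 lower (906 at an unadjusted p under 0.05); within 50 kb of an end 14 were higher, with a median of 0.63, and 1 lower. Scaled by internal spread the split turned to 181 higher and 118 lower of 299. Zones at 20 to 30 kb from the left end of chromosome 3 (0.67), 10 to 15 kb from the right end of chromosome 11 (0.64), 30 to 50 kb from the right end of chromosome 1 (0.54) and 20 to 30 kb from the right end of chromosome 6 (0.44) were higher, and the zone at the ADH4 breakpoint lower (-2.92), 5 of 144 in all; scaling left 4 higher and 0 lower, and the deposit as a block gave 13 (12 higher). HML (6.32) and HMR (5.98) were below their WT means, YFR057W (6.77) was not, and HMRA1 differed by -1.32 (SE 0.68, adjusted p = 0.281). The gene count depended on arrays and fit: 305 without WT replicate 1, 231 without WT replicate 2, 0 with only these groups or the first deposit in the fit, and 129 with the deposit as a block.

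SIR2 with SIR3 overexpression was compared with pGPD-SIR3 in yAT2476, a strain that also lacks the truncated end. Signal was higher 20 kb and more from some ends than on the single yAT2476 array, but lower on average nearer the ends. Zone means were 4.27 against 5.35 at 0 to 5 kb, 3.82 against 4.62 at 5 to 10 kb and 3.19 against 3.77 at 10 to 15 kb. Of these zones, 1 of 21 at 5 to 10 kb passed the threshold as lower, and 0 in the other classes. HMR (4.196 against 5.213) and YFR057W (4.636 against 5.938) were lower too, without a test. On the left end of chromosome 12, the sulfonate dioxygenase gene JLP1 (26.4 kb from the end) rose by 2.99 (SE 0.43) and HSU1 by 2.58. That end was covered over 30 and 23 kb on the 2 arrays, against 15 kb in yAT2476 and 23 kb on both yAT1254 arrays, so the yAT2476 array was low here too. On the right end of chromosome 14, BSC5 went from 0.21 to 3.72 ± 0.51 (SD, n = 2), a rise of 3.51 (SE 0.28, limma adjusted p = 1.24e-05), and YNR068C rose by 3.24. BSC5 was at 4.54 ± 0.28 with pGPD-SIR3 in yAT1254, and this end was covered over 19 kb both there and with SIR2 and SIR3 but over 13 kb in yAT2476, so that rise rests on yAT2476 being low. ZPS1 (1.96), FIT1 (1.44), HSP31 (1.25, the 1 measured HSP31 paralog), DAN4 (1.25) and the hexose transporter gene HXT8 (1.12) rose 27.5 to 35 kb from ends. Zones at 20 to 30 kb rose on the left end of chromosome 12 (2.43, SE 0.44), the right ends of chromosomes 14 (1.88) and 4 (1.26) and the left end of chromosome 5 (0.77), and the zone at 30 to 50 kb on the left end of chromosome 9 (0.49); the zone at 5 to 10 kb on the right end of chromosome 13 was lower (-1.65).

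Internal rises with SIR2 and SIR3 included ADE2 (2.91, SE 0.19), the SIR2 gene (2.31, SE 0.15), the spore wall gene CRR1 (1.96, SE 0.13), HXT10 (1.22), the glycolytic genes TDH1 (1.10), PDC1 (0.90) and ENO1 (0.78), and the mannoprotein genes TIR3 (0.91) and TIR4 (0.63). Of 4 measured mannoprotein genes 3 rose (4 adjusted over the list alone; adjusted p = 0.0788 with an estimated correlation). In the sugar list the median was 0.20 and the mean -0.07. Lower were YPS6 (-1.80), OCA4 (-1.69, SE 0.26), CHA1 (-1.33), STE2 (-1.09), PHO5 (-0.63) and 24 of 68 ribosomal protein genes (44 adjusted over the list alone; median -0.61; adjusted p = 0.217 with an estimated correlation), among them RPL10 (-1.22), RPL28 (-1.19), RPL22A (-1.09) and RPL13A (-1.07). STE2 and the ribosomal protein list were higher in yAT2476 than in yAT1254, by 1.22 and a median of 0.60, and both contrasts rest on the same yAT2476 array. The SIR3 gene differed by -0.07 (SE 0.20, adjusted p = 0.873). Of 396 calls 309 were higher and 87 lower (1035 at an unadjusted p under 0.05). The replicates of the SIR2 and SIR3 group covered 625 kb in the first deposit and 511 kb in the later one. The count was 103 in the first deposit alone, 348 with the deposit as a block, and 249 and 237 without replicate 1 or 2 of that group; the 6 zone calls went to 0 with scaling and to 13 with the block.

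The A2Q mutant, a change of the second residue of Sir3, was expressed from the GPD promoter and compared with WT and with pGPD-SIR3. Against WT, Sir3 signal was lower at the WT targets. YCL074W (probes 2958 to 3571, 3.3 kb from the left end of chromosome 3) went from 6.96 ± 0.34 to 0.47 ± 0.16 (SD, n = 2 each), a difference of -6.49 (SE 0.42, limma adjusted p = 2.63e-06). HMRA1 differed by -5.76 (SE 0.56), IMD2, an IMP dehydrogenase gene, by -4.93, CHA1 by -4.75, COS8 by -3.73, YFR018C by -3.14, YIR043C by -3.10 and COS10 by -3.06. AAD3 (-2.66) and PHO3 (-0.73) were the called members of their lists. Signal remained at HML (2.87 ± 0.05), HMR (1.67 ± 0.08), YFR057W (1.45 ± 0.03) and the rDNA (1.06 ± 0.09). Over SIR3 itself A2Q was at 0.54 ± 0.28, 0.23 above WT (SE 0.16, adjusted p = 0.434).

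Of 67 calls between A2Q and WT 47 were lower and 20 higher (884 at an unadjusted p under 0.05), and within 50 kb of an end 19 were lower and 0 higher. The higher ones were all internal, with a median of 0.41: PRM15 (0.59), the helicase gene MSS116 (0.54), RBG1 (0.54), LIP5 (0.51), GUF1 (0.48), CLG1 (0.47), YDR341C (0.45) and CGI121 (0.43). Scaled by internal spread the calls were 69 lower and 49 higher. Of 144 zones 45 were lower and 0 higher, the largest on the left end of chromosome 3 at 0 to 5 kb (-6.28, SE 0.47) and 5 to 10 kb (-5.90). Scaling left fewer zone calls, as given further down. Of 4 COS genes 2 were lower (adjusted p = 0.324 with an estimated correlation). All arrays lay in the first deposit, which alone gave 42 calls, all lower; the deposit as a block gave 124 (88 lower). Counts were 706 without WT replicate 1, 34 without WT replicate 2 and 17 without A2Q replicate 1.

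Against pGPD-SIR3 the lower signal in A2Q covered every distance class. YCR102C differed by -6.58 (SE 0.43, limma adjusted p = 4.74e-07), from 6.33 ± 0.53 to -0.25 ± 0.26 (SD, n = 2 each), the alcohol dehydrogenase gene ADH7 by -6.58, BDS1 by -6.53, YOR389W by -6.40, YOL162W by -6.40, COS10 by -6.31, YCL074W by -6.31 and YIR042C by -6.31. All 10 zones at 0 to 5 kb, all 21 at 5 to 10 kb and 14 of 32 at 30 to 50 kb were lower, 111 of 144 in all. Of 10 sugar genes 9 were lower (MAL33 -5.72, MAL31 -4.86, IMA5 -3.72), of 4 COS genes 3, of 6 phosphate genes 4 (PHO89 -4.03, PHO3 -2.35, PHO5 -1.56) and of 3 aryl-alcohol genes 3 (AAD3 -5.88). The counts adjusted over the list alone were 9, 3, 4 and 3. These camera calls held with an estimated correlation (adjusted p = 0.0362 for the sugar, COS and phosphate lists and 0.0486 for the aryl-alcohol list). For iron genes, 7 of 12 lower with ARN2 at -5.99, ENB1 at -4.59 and FRE2 at -3.99, it was 0.0639.

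Elsewhere A2Q was below pGPD-SIR3 at HMRA1 (-5.02), the SIR3 gene (-3.30, SE 0.16), FLO9 (-2.21), CDC19 (-1.30), PMA1 (-1.26), ENO2 (-0.78), PDC1 (-0.68), the vitamin B6 gene SNZ1 (-0.57, the 1 measured thiamine and vitamin B6 gene) and HSP31 (-0.57). The small rises were internal: CBF5 (0.44), CLG1 (0.44), RPL22B (0.43), RPC40 (0.42), BUD16 (0.41), RPL17B (0.40), ERD1 (0.39), PAN3 (0.39) and the origin recognition gene ORC1 (0.31). Of 401 calls 344 were lower and 57 higher (1008 at an unadjusted p under 0.05). Both groups lay in the first deposit, which alone gave 261 calls, all lower; without pGPD-SIR3 replicate 2 there were 240, and with the deposit as a block 407.

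pGPD-SIR3 cells released from NAM for 8 h were compared with the same strain in steady growth. Signal was lower at many ends after release. DLD3 went from 6.03 ± 0.36 to 1.59 ± 0.01 (SD, n = 2 each), a difference of -4.44 (SE 0.41, limma adjusted p = 0.000242), and RMD6 from 6.48 ± 0.28 to 2.75 ± 0.31 (-3.73). The arsenite transporter gene ARR3 and its regulator ARR1, on the right end of chromosome 16, differed by -4.34 and -3.39. COS9 (-3.61), MAL31 (-3.41), MAL33 (-3.34) and FRE2 (-3.06) were lower. HMRA1 differed by -0.88 (SE 0.56, adjusted p = 0.349) and the SIR3 gene by 0.03 (SE 0.16, adjusted p = 0.922). Of the sugar genes 7 of 10 were lower (7 adjusted over the list alone; MAL11 -2.31; adjusted p = 0.11 with an estimated correlation), of the iron genes 6 of 12 (8 adjusted over the list alone; ENB1 -2.96, ARN2 -1.53; adjusted p = 0.115). PHO89 (-2.67), COS10 (-1.61), FLO9 (-1.50), AAD6 (-1.35), FLO5 (-0.80), PHO3 (-0.66) and TIR4 (-0.48) were lower too.

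Ribosomal protein genes were higher after release: 40 of 68 over all genes and 56 adjusted over the list alone, with a median of 0.62. RPS9A rose by 1.07 (SE 0.15), RPS17A by 1.04, RPS7B by 1.02, RPL37A by 0.93, RPS9B by 0.90 and RPL22B by 0.89, and the fatty acid desaturase gene OLE1 (0.92) and EFB1 (0.59) also rose. The list's camera call had an adjusted p of 0.11 with an estimated correlation. This list was also higher, by a similar median, in yAT2476 than in yAT1254 without NAM. Both contrasts share the yAT1254 arrays, and the second rests on the single yAT2476 array. Whether the rise of this list is particular to release therefore cannot be told. In all 362 genes were called, 154 higher and 208 lower (1092 at an unadjusted p under 0.05); within 50 kb of an end 73 were lower, with a median of -1.53, and 9 higher. Of 144 zones 61 were lower and 0 higher, the largest at 15 to 20 kb from the left end of chromosome 5 (-4.14, SE 0.38). Both NAM arrays lay in the later deposit and both steady-growth arrays in the first, so no within-deposit value can be had. With the deposit as a block, 135 genes (25 higher, 110 lower), 10 zones and 9 ribosomal protein genes (median 0.46) were called. Of the 82 genes called within 50 kb of an end without the block 22 kept their call. The median difference of these 82 went from -1.456 to -0.827. Scaling also left fewer zone calls, as given further down. The gene count was 73 and 72 without pGPD-SIR3 replicate 1 or 2, and 16 and 110 without NAM replicate 1 or 2.

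The arrays labelled dot1 were compared with pGPD-SIR3, both after release from NAM and both in the later deposit. Sir3 signal was lower near the ends and higher in many zones 20 to 50 kb from them, and internal genes went both ways (995 higher, 935 lower). The largest rise was at NDI1, a mitochondrial NADH dehydrogenase gene 29.1 kb from the left end of chromosome 13 (probes 28459 to 29623). It went from 0.11 ± 0.04 to 3.34 ± 0.32 (SD, n = 2 each), a difference of 3.23 (SE 0.13, limma adjusted p = 6.23e-09). On the same chromosome the phosphatase regulator gene GLC8 (3.14), the Elongator gene ELP6 (3.12) and the RNA-binding protein gene NAB6 (2.97, SE 0.10) rose. The IQGAP gene IQG1 on chromosome 16 (3.04), PKC1 on chromosome 2 (2.69), the chitin synthase gene CHS1 on chromosome 14 (2.66) and the CCR4-NOT gene CDC39 on chromosome 3 (2.56) rose, as did the RNA polymerase II gene RPO21 (1.89, SE 0.12), PHO84 (1.45), FRE5 (0.98), TUB1 (0.67) and the SIR2 gene (0.67, SE 0.12). Among the internal controls 4 of 11 were higher and 2 lower; ACT1 rose by 0.63 (SE 0.12, adjusted p = 0.00102) but turned to -0.933 MADs (adjusted p = 0.133) with arrays scaled by their internal spread.

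Lower in dot1 were subtelomeric genes bound after release: YFR054C (-2.85, SE 0.52), YOL162W (-2.55), SEO1 (-2.51), DFP4 (-2.50), GDH3 (-2.35) and BDS1 (-2.10). HMRA1 was lower by -1.77 (SE 0.56, adjusted p = 0.0186) and the SIR3 gene by -1.05 (SE 0.16). Of 4 COS genes, COS9 (-1.70), COS10 (-1.33) and COS8 (-1.19) were lower, whereas COS111, 181.1 kb from an end and named after its value was seen, was higher by 1.04. IMA5 (-1.79), IMA1 (-0.95) and HXT8 (-0.92) were among 5 of 10 sugar genes, and FLO9 (-1.13), FLO1 (-0.88) and FLO5 (-0.67) among 4 of 5 flocculins. All 3 aryl-alcohol genes (AAD3 -1.25, AAD6 -1.20, AAD4 -0.90), PHO5 (-0.94), PHO3 (-0.81), TIR3 (-0.91), TIR1 (-0.61), ENB1 (-1.19) and ARN2 (-1.09) were lower. Of ribosomal protein genes 47 of 68 were lower (48 adjusted over the list alone; RPL10 -1.37, RPL28 -1.19, RPL34A -1.12) and of highly transcribed genes 8 of 11 (8 adjusted over the list alone; FBA1 -0.77, ENO2 -0.74, TDH3 -0.73). Both lists' camera calls had an adjusted p of 0.743 with an estimated correlation.

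By distance, 7 of 10 zones at 0 to 5 kb were lower in dot1 and 0 higher, while at 30 to 50 kb 17 of 32 were higher and 5 lower; in all 34 were higher and 49 lower, and with scaling 23 and 62. The largest zone rises were at 20 to 30 kb from the right end of chromosome 13 (2.75, SE 0.14), 15 to 20 kb from the left end of chromosome 2 (2.60) and 30 to 50 kb from the left end of chromosome 13 (2.39), and the largest falls at 10 to 20 kb from the left end of chromosome 15 (-3.05 and -2.76). The left end of chromosome 13 was covered over 39.5 of 42 kb in dot1 and 7 kb in its counterpart, and that of chromosome 2 over 26.5 and 7.5 kb. Covered length was 441 ± 35.4 kb in dot1 and 427.5 ± 43.1 kb in its counterpart, a difference within the spread of the arrays. With a threshold of log2 1 on every array, chosen after seeing the data, it was 616.5 and 397.5 kb, whereas with 4 MADs the order turned, to 319 and 377.5 kb. Of 2172 called genes 1161 were higher and 1011 lower (2433 at an unadjusted p under 0.05), and 1930 lay over 50 kb from the ends. The MAD of internal genes was 0.516 and 0.528 on the dot1 arrays and 0.185 to 0.284 on all others; scaled by it 944 genes were called, 544 higher. The later deposit alone gave 2519 calls and the deposit as a block 2195.

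Across groups, the most strongly bound loci showed no steady rise with SIR3 expression, in a series that mixes strain backgrounds (WT and yAT1254 share one). HMR was at 7.24 ± 0.19 in WT, 4.96 ± 0.32 with pADH-SIR3, 5.12 ± 0.82 with pTEF-SIR3, 6.37 ± 0.46 with pGPD-SIR3 and 3.81 ± 0.55 in dot1 (SD, n = 2 each), and at 4.98 and 5.21 with pGPD-SIR3 in yAT2554 and yAT2476. YFR057W was at 5.98 ± 0.14, 5.81 ± 0.53, 6.67 ± 0.12 and 3.57 ± 0.49 in the same groups after WT, and at 5.32 and 5.94 in yAT2554 and yAT2476. Signal at the rDNA probes lay between 2.71 and 3.88 in all groups except A2Q (1.06 ± 0.09) and dot1 (1.60 ± 0.06). The SIR3 gene was at 0.31 ± 0.14 in WT, then 0.92 ± 0.07, 3.20 ± 0.01 and 3.84 ± 0.13 along the series, but at 2.55 and 2.83 in yAT2554 and yAT2476, below pTEF-SIR3, so the last step held only in yAT1254.

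**Figure D3:**
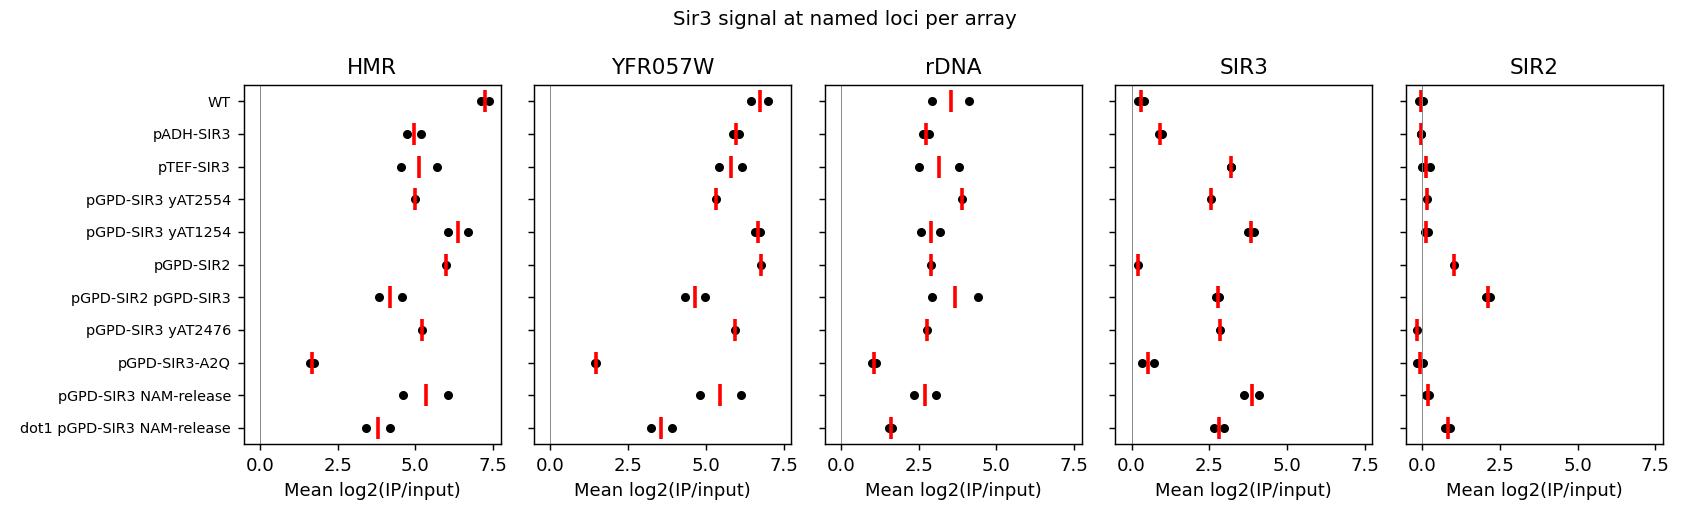
Mean log2 ratio of precipitated over input DNA (x axis) at HMR, YFR057W, the rDNA, SIR3 and SIR2 for each group (y axis), with points for arrays and a red bar for the group mean. At SIR3 the means run from 0.31 in WT to 3.84 with pGPD-SIR3, and at HMR from 1.67 in A2Q to 7.24 in WT.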

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

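Of the tests in this part, the interaction with yAT1254, those on the zones within 10 kb of an end, on the internal spread, on the DOT1 probes, on the A2Q signal over SIR3 and on the SIR2 gene, and the split by distance in the deposit test were chosen after the result was seen. The rules that label the deposit, wider-spread, mislabelling and transcription tests were also changed after their values were seen.

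The effect of SIR3 overexpression was compared between strains with and without SIR2 overexpression by an interaction test in limma. In all 257 genes differed. The effect with SIR2 minus that without was positive for 191 and negative for 66. This sign does not tell which effect was larger in size. At TRP3 the effect was -0.10 with and -1.07 without SIR2 overexpression, and at MRC1 -1.29 and -0.15. Of the 257 genes, 32 lay within 50 kb of an end and 225 further in. The largest were BSC5, with a difference of effects of 3.54 (SE 0.40, limma adjusted p = 0.00111), the sulfonate dioxygenase gene JLP1 with 3.24 (SE 0.60, adjusted p = 0.00998) and YNR068C with 2.69 (SE 0.49, adjusted p = 0.00875). Smaller effects in the SIR2 background were seen at OCA4 (-2.31), PUG1 (-2.12) and GAB1 (-1.95). Many of the genes further in lay on chromosome 12, which holds the rDNA, nearer its right end. Among them were CAR2 (2.64), DIC1 (2.26) and CRR1 (1.81), while GAB1, nearer the same end, went the other way. Whether this stretch held more genes than its share was not tested. With pGPD-SIR3 taken from yAT1254, 120 genes were called (86 positive, 34 negative). That fit shares 3 of its 4 groups with the first, and 76 of the 257 kept their call. BSC5 turned to -0.78 (SE 0.36, adjusted p = 0.247) and YNR068C to -0.45 (adjusted p = 0.603), so both rested on the yAT2476 array, HSU1 went from 2.53 to 1.56 (adjusted p = 0.0871), while JLP1 stayed at 2.37 (adjusted p = 0.0411), and OCA4 (-3.00), PUG1 (-2.11) and GAB1 (-1.85) stayed smaller. CAR2 also turned, from 2.64 to -0.125, and YLL056C went from 2.33 to 1.61. Of the 257 genes 10 changed sign. Both fits share the single pGPD-SIR2 array, so the second cannot show what rests on that array. RPP0 (1.70), LAT1 (1.97) and SNF4 (1.45), lower there than in WT, had positive interactions in the first fit. SPO74 (-0.93) and MRC1 (-1.14), higher there, had negative ones, whereas ADE2 (1.93) and SIR2 (1.27), also higher there, had positive ones. The interaction took pGPD-SIR3 in yAT2476 and pGPD-SIR2 from 1 array each, and the 4 strains differ in more than SIR2 and SIR3. The rDNA insertion and the chromosome 7 end are among these differences, so it cannot be put down to SIR2.

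The first pattern weighed was the 362 genes that differed between release from NAM and steady growth, where each group lay wholly in a different deposit. With the deposit as a block, estimated from the 3 groups with arrays in both, the median size of the difference went from 0.532 to 0.494, a ratio of 0.929 that lay above the bound of 0.75 set beforehand as speaking against the deposits, but that ratio pools 2 parts that behaved differently. Over the 280 internal genes the median ratio was 0.987 (lower quartile 0.821). This argues against a deposit shift shared with those 3 groups as the whole cause there. It cannot speak to a shift between deposits that is particular to this strain. Only 87 of these calls held: the median size went from 0.477 to 0.446 and the median SE from 0.107 to 0.134. Of the 193 that ended, 187 had a wider SE and 138 a smaller size. Over the 82 genes within 50 kb of an end the ratio was 0.726 (lower quartile 0.581), the median difference went from -1.456 to -0.827 and 22 calls held, so there the release and the deposits cannot be told apart. The ribosomal protein median went from 0.621 to 0.464, and an effect of the release, the difference named by the design, stays open for both parts.

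The second pattern was the signal far from the ends on the arrays labelled dot1. Of 31 zones within 10 kb of an end 19 were lower and 0 higher on these arrays. A wider spread of the same ratios alone would raise signal there. However, this fall was known before it was made a test. A wider spread together with weaker signal at strongly bound sites, such as HMR (3.81 against 5.33), would also give it. The correlation of 0.536 between the group means over internal genes (0.924 and 0.981 between replicates) narrowly missed the bound of 0.5 set beforehand. The correlation and the zones near the ends therefore do not decide on a wider spread. After division by the internal spread 18 zones 20 to 50 kb from an end were still higher, which argues against that spread as the whole cause there. A mislabelled strain with DOT1 present needs measured DOT1 probes, and 9 of 10 values were measured. Since 108 of 120 values within PPR1 were measured too on arrays labelled as lacking it, such a strain and a deletion that spares the probes cannot be told apart, and loss of Dot1, the difference named by the design, stays open and untested.

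The third pattern was the signal over the SIR3 gene in pGPD-SIR3, at 3.84. The 9 tested genes within 20 kb on the side of the end had a mean of 0.303 and at most 0.517 (RIF2), and the 7 on the other side a mean of 0.950, which argues against spread from the right end of chromosome 12. The A2Q arrays, with the same promoter, lay 0.23 (SE 0.16) above WT at SIR3, but A2Q was also below pGPD-SIR3 at 3 of 11 highly transcribed genes with unchanged promoters, such as CDC19 (-1.30), and expression of the mutant was not measured here, so transcription from the GPD promoter alone and binding of the protein cannot be told apart. The SIR2 gene under the same promoter, without SIR3 overexpression, lay 1.04 (SE 0.15) above WT, but on 1 array, which is too little to decide. With SIR2 and SIR3 overexpressed together, signal over the SIR2 gene was at 2.12 ± 0.11 (SD, n = 2), against -0.15 on the yAT2476 array. A comparison of SIR2 with and without SIR3 overexpression still rests on the single pGPD-SIR2 array, so it does not decide either. Local binding of the overexpressed protein and a technical effect of the promoter cassette on nearby probes stay open and were not tested.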

How the results depend on the processing

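Alternatives with probes at least 300 bp inside the gene, probes measured on each array, either deposit alone, a fixed log2 threshold and the interaction with pGPD-SIR3 from yAT1254 were chosen after seeing the data, the others before. For single named genes, apart from the interaction given further down, 372 results were set against 4719 alternatives: 4137 kept direction and side of the threshold, 577 kept the direction but no longer passed, 4 came to pass and 1 turned. The one that turned was ACT1 in dot1 after release, from 0.63 to -0.933 MADs (adjusted p = 0.133) on scaled arrays; the scale of the dot1 arrays, whose internal spread is wider, differs by construction. Of the changes to a weaker call, 280 came with leaving out single arrays (45 and 44 without pGPD-SIR3 replicate 1 or 2, 35 without WT replicate 2), 63 with scaling, 85 with the first deposit alone, 79 with only the compared groups in the fit and 23 with the deposit as a block. Of the 282 alternatives to counts and lengths, 148 stayed near the main value and 134 moved; near means within 1.5 times for counts and within 1 SD of the replicates for lengths, where any change counts for groups of 1 array. Unless the setting itself explains a change, the cause was not tested.

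With arrays divided by the internal MAD, called genes went from 39 to 66 for pADH-SIR3 against WT, 158 to 41 for pTEF-SIR3 against pADH-SIR3, 3 to 0 for yAT2554 against yAT1254, 99 to 299 for pGPD-SIR2 against WT, 67 to 118 for A2Q against WT and 2172 to 944 for dot1. Zones went from 72 to 39 for pTEF-SIR3 against pADH-SIR3, 3 to 0 for yAT2554 against yAT1254, 6 to 0 for SIR2 with SIR3 against yAT2476, 45 to 22 for A2Q against WT and 61 to 23 for NAM release.

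At least 4 probes per gene, which tests fewer genes, gave 11 calls for pADH-SIR3 against WT, 188 for pTEF-SIR3 against WT, 177 for pGPD-SIR3 against WT and 90 for pTEF-SIR3 against pADH-SIR3. It gave 105 for yAT2476 against yAT1254, 232 for SIR2 with SIR3, 245 for A2Q against pGPD-SIR3 and 186 for NAM release. Probes at least 300 bp inside the gene, again with fewer genes, gave 21, 221 and 210 for pADH-SIR3, pTEF-SIR3 and pGPD-SIR3 against WT, 5 for yAT2554 and 124 for yAT2476 against yAT1254, 258 for SIR2 with SIR3, 251 for A2Q against pGPD-SIR3 and 193 for NAM release. Single probes gave 96 for yAT2476 against yAT1254, 179 for SIR2 with SIR3, 250 for A2Q against pGPD-SIR3 and 166 for NAM release. For yAT2554 against yAT1254 the authors' filled values gave 8 calls, probes measured on each array 6 and slide as a random block 1.

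With only the compared groups in the fit, and so fewer arrays, calls were 19, 130 and 147 for pADH-SIR3, pTEF-SIR3 and pGPD-SIR3 against WT, 36 for yAT2554 and 477 for yAT2476 against yAT1254, 0 for pGPD-SIR2, 118 for SIR2 with SIR3, 36 for A2Q against WT and 664 for NAM release. The first deposit alone gave 142 for pTEF-SIR3 and 194 for pGPD-SIR3 against WT, 77 for pTEF-SIR3 against pADH-SIR3, 2 for yAT2554 against pTEF-SIR3, and 8 and 55 for yAT2554 and yAT2476 against yAT1254. It gave 0 for pGPD-SIR2, 103 for SIR2 with SIR3, 42 for A2Q against WT and 261 for A2Q against pGPD-SIR3. For NAM release neither deposit alone gives a value.

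With the deposit as a block, calls were 6 for yAT2554 against yAT1254, 124 for A2Q against WT and 135 for NAM release, and zones 5 for yAT2554 against yAT1254, 13 for pGPD-SIR2, 13 for SIR2 with SIR3 and 10 for NAM release. With replicate number as a block, which pairs nothing in the labels, calls were 5 for yAT2554 against yAT1254 and 61 for pGPD-SIR2.

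Leaving out each array in turn, with a lone array assumed to vary like the other groups, gave 23 to 296 calls for pADH-SIR3, 204 to 740 for pTEF-SIR3 and 160 to 834 for pGPD-SIR3 against WT, the highest each time without WT replicate 1. The range was 93 to 156 for pTEF-SIR3 against pADH-SIR3, 0 to 2 for yAT2554 against pTEF-SIR3, 1 to 3 for yAT2554 and 59 to 62 for yAT2476 against yAT1254, and 231 to 305 for pGPD-SIR2. It was 237 to 249 for SIR2 with SIR3, 17 to 706 for A2Q against WT, 240 to 304 for A2Q against pGPD-SIR3, 16 to 110 for NAM release and 1589 to 1652 for dot1. Leaving out the array of a group of 1 gives no value.

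Covered length moved with its threshold and bin size, as a lower threshold and wider bins count more by construction. With 2 MADs it was 357 kb for WT, 379.5 for pADH-SIR3, 591.5 for pTEF-SIR3, 599 for yAT2554, 607.5 for pGPD-SIR3, 586 for pGPD-SIR2, 649 for SIR2 with SIR3, 586 for yAT2476, 107 for A2Q, 520 for NAM release and 594 for dot1. With 2-kb bins it was 355, 386, 589, 618, 615, 528, 655, 586, 99, 490 and 493 kb in that order. With 4 MADs it was 272 kb for pADH-SIR3, 461.5 for pTEF-SIR3, 485 for yAT2554, 481.5 for pGPD-SIR3, 311 for pGPD-SIR2, 460 for yAT2476, 45.5 for A2Q, 377.5 for NAM release and 319 for dot1, so the last 2 changed places. The authors' filled values gave 331 kb for pADH-SIR3, 544 for pTEF-SIR3, 564 for yAT2554, 561 for pGPD-SIR3, 446 for pGPD-SIR2, 529 for yAT2476 and 67.5 for A2Q. The fixed log2 threshold of 1 gave 267 kb for pADH-SIR3, 498 for yAT2554, 487.5 for pGPD-SIR3, 313 for pGPD-SIR2, 481 for yAT2476, 46.5 for A2Q and 616.5 for dot1.

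In the interaction of SIR2 and SIR3 overexpression, pGPD-SIR3 from yAT1254 instead of the single yAT2476 array gave 120 genes instead of 257. BSC5 turned from 3.54 to -0.78 (adjusted p = 0.247) and YNR068C from 2.69 to -0.45 (adjusted p = 0.603), since both were low on the yAT2476 array, while JLP1 went from 3.24 to 2.37 (adjusted p = 0.0411).

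Medians near 0 changed sign with scaling for ribosomal proteins between pGPD-SIR3 and WT, for the internal controls in 2 comparisons and for the altered loci in dot1; no other list reported here did so. Background correction, loess, a filter on dim probes and a filter on repeated sequence were not run, since channel intensities and probe sequences were not used here. The low correlation of replicates, 0.730 in A2Q and 0.743 in WT, limits what can be read from these groups. Its cause was not tested. WT had the highest signal of all groups at HML (7.65) and HMR (7.24), and its arrays were covered over 304 and 223 kb.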

Other observations

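Genes over 50 kb from the ends also exceeded the threshold of their arrays: 25 in WT, 79 with pADH-SIR3, 127 with pTEF-SIR3, 124 with pGPD-SIR3, 153 with SIR2 and SIR3, and 21 in A2Q. The WT count was near that of A2Q, and no mock precipitation was used here to set a background. In WT 61 genes exceeded 3 internal MADs on every array, 36 of them within 50 kb of an end; with pTEF-SIR3 these were 233 and 106, with pGPD-SIR3 246 and 122, and in A2Q 24 and 3. After release from NAM the counts were 234 and 92, and on the arrays labelled dot1 232 and 116. These thresholds follow the spread of each array, so counts from groups of 1 array (263 in yAT2554 and in yAT2476, 190 with pGPD-SIR2) are not set against those of 2.

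Single ends, picked after their values were seen, differed in how far signal reached. On the arrays labelled dot1 the left end of chromosome 3 was covered over 43.5 kb against 22.5 kb in its counterpart after release, and the right end of chromosome 11 over 20 against 6.5 kb. The left end of chromosome 1 was covered over 8 against 24.5 kb and that of chromosome 10 over 1 against 6.5 kb. With SIR2 and SIR3 the right end of chromosome 10 was covered over 15 kb, against 5 kb in yAT2476 and 3.5 kb with pGPD-SIR3 in yAT1254. None of these values was tested.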
